A study of Mus musculus with 2 samples.

How the data were processed

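Total RNA from the adrenal gland was sequenced in 2 adult male mice of the strain B6CASTF1/J, the F1 hybrid of C57BL/6J and CAST/EiJ parents, at 8 to 10 months of age. The labels name 1 group, number the biological replicates 1 and 2, and tie them to separate animals (animal 2 and animal 4 of the submitters' numbering). Each library started from 300 ng of RNA, was made with a directional (strand-keeping) RNA library kit and carried ERCC spike-ins, synthetic RNAs of known sequence, in a profile meant for libraries reduced in ribosomal RNA, per the labels. No treatment, time point or second group is named, so the comparisons were of gene groups within each gland and of replicate 2 with replicate 1.

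The deposited gene tables hold expected counts (estimated counts that need not be whole, not normalized), and their column names are those RSEM writes, per the file headers. The same tables give TPM, which the authors computed over all genes, spike-ins and further entries so that each column has the same sum. Posterior means and standard deviations of the count and credibility bounds of the TPM stand beside them, per the file headers. The deposited transcript tables give expected counts, TPM and the percent of its gene's TPM that each transcript takes. A further deposited transcript table per library holds estimated counts and TPM under the column names kallisto writes, per the file headers. The text accompanying the deposited tables gives the mm10 assembly with GENCODE M21. It says that the first set was derived from a transcriptome alignment and the other from the reads and an index. Versions of the aligner and of both quantifiers are not given in the sources used here. Each library was quantified alone and replicates were not pooled.

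All 55536 annotated gene IDs matched GENCODE M21 with their version, and gene names, types and coordinates came from that annotation. The gene tables also hold 96 ERCC entries, 1 entry for phiX174 (a sequencing control) and 26248 entries named by a bare number that neither the headers nor the labels explain. These were kept out of library sizes and gene results. The kallisto-format tables list 141767 annotated transcripts against 141862 in the RSEM-format tables, and 86 genes have no transcript in the former.

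Expected counts on annotated genes summed to 29994901 in replicate 1 and 33987434 in replicate 2. A count of 0 allows up to 3 counts, or 0.100 and 0.0883 CPM, counts scaled to a common library total. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. TPM were used as deposited for levels, given as mean ± SD over the 2 animals. A gene was called detected at 1 TPM or more in both.

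For the comparison of replicates, expected counts were scaled with TMM factors from edgeR 4.0.16 (R 4.3.3). DESeq2 1.42.0 gave size factors for an alternative scaling only. Counts were rounded to whole numbers for these factors and for folds, but not for log2 ratios. Log2 ratios are of CPM + 1, replicate 2 over replicate 1, which understates differences of genes with few counts. Folds are ratios of scaled counts without the added 1, with exact conditional binomial 95% intervals. Against a count of 0 they were computed with 3 counts in its place. Their interval then has a lower end only, which can lie below that fold. With 1 animal on each side no p-value was computed. The smallest two-sided p that an exact paired permutation over 2 animals allows is 0.5. Genes were counted as differing where nuclear genes with a mean of at least 100 counts lay at least 2-fold apart and the interval excluded equality.

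Each gene list was summarised by the median log2 ratio of its members with a mean of at least 10 counts. That median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, drawn with a fixed seed. Lists outside the central 95% are called above or below the random range, which describes these 2 libraries and is no test of conditions. Lists with fewer than 3 such members were not placed.

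Before the data were examined, 34 lists with 362 entries were fixed, and every entry matched by symbol. They cover steroidogenesis, the zona glomerulosa, the zona fasciculata, the X-zone, chromaffin cells, Schwann and sustentacular cells, capsule and fibroblasts, endothelium, smooth muscle and pericytes, macrophages, lymphocytes, class II antigen presentation, erythroid cells, brown adipocytes, adipocytes, kidney, liver, pancreas and skeletal muscle. They also cover cholesterol synthesis, immediate early genes, heat shock, glucocorticoid targets, clock genes of the E-box phase, clock genes in antiphase to them, interferon-stimulated genes, proliferation, mitochondrial mRNAs, Y-linked genes, X inactivation, imprinted genes, housekeeping genes, structural noncoding RNAs and replication-dependent histones. The rule for named genes, fixed with them, took the 4 members of each list with the highest mean TPM. It also took the 15 coding and 5 noncoding genes with the highest TPM, the 12 highest and 12 lowest log2 ratios among nuclear genes with at least 100 counts, and the 4 members furthest from 0 in each list outside the random range. The 5 genes furthest apart in each direction between the quantifiers (at 5 TPM or more) and the main transcripts of the leading steroidogenesis and chromaffin genes completed it. Genes named outside the rule are said to be so, and the values of some genes that the rule takes are not reported here.

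Reads shared by near-identical copies can be divided arbitrarily by either quantifier. List members taken by gene family to have such copies (globin genes, Hspa1a and Hspa1b, Cyp11b1 and Cyp11b2, Hsd3b1 and Hsd3b6, Cyp21a1, Mup3, Serpina1a, Prss2, Rn7s1 and Rn7s2, and histones) were left out in one alternative. Separately, among genes with a mean of at least 100 counts, an estimated count was called uncertain where its posterior SD exceeded 5% of its posterior mean, which holds for few of these members. Reads from CAST/EiJ chromosomes were assigned to a reference built on C57BL/6J, and the effect of strain variants on mapping was not assessed.

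The quantifiers were compared by the ratio of TPM (pseudocount 0.01) over genes with at least 1 TPM by either in both animals. A gene was called apart where the ratio reached 2-fold in the same direction in both. Spike-in shares carry exact Clopper-Pearson 95% intervals.

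The comparison of replicates was tested on simulated counts drawn from the real means and library sizes over 12822 genes. Of 50 genes simulated at each true fold, 49 were called at 3-fold, 44 at 4-fold, 48 at 8-fold and 0 at 1.5-fold, below the threshold. The 1, 6 and 2 genes missed at the larger folds fell under the minimum count. None (0) of 12611 unchanged genes was called, and the interval held the true fold for 95.0% of genes. A list of 20 genes simulated 1.4-fold higher lay at percentile 100, and 2 of 100 unchanged lists fell outside the central 95%. The simulation contains counting noise only, not variation between animals.

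Alternatives changed the scaling, pseudocount, count minimum, fold threshold, detection level, quantifier, posterior mean values, list members with near-identical copies, the TPM denominator and the animals included. After the data were seen, 4 were added, which restricted counts of genes to well-determined estimates, removed list members expressed in fat, removed the trend with GC content and transcript length, and used coding genes only as matched background. Also chosen after the main results were 4 lists of independent fat genes, chaperones, cAMP targets and sterol targets, the mitochondrial mRNAs summed with their nuclear copies, and 6 further lists. Those hold hormone and neurotransmitter receptors, nicotinic receptor subunits, WNT signalling and cortical progenitors, lipid droplet and sterol transport, steroid-converting enzymes, and antioxidant enzymes. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. The free text deposited with the tables holds no measurements and was used only for the assembly, the annotation and the origin of the tables.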

Results

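The data describe RNA of the whole adrenal gland, which combines a steroid-producing cortex and a catecholamine-producing medulla, in 2 male B6CASTF1/J mice. Replicate 1 held 29994901 and replicate 2 33987434 expected counts on annotated genes. Genes with at least 1 TPM numbered 14544 in replicate 1 and 14731 in replicate 2, with 13921 in both, among them 12385 of the 22015 nuclear protein-coding genes. The labels give 2 separate animals. A second deposit of the same library would differ by sampling noise alone, which was not so here (chi-square per degree of freedom of 53.2 over 18181 nuclear genes); the value says nothing more about the animals. All levels below are mean TPM ± SD over n = 2 animals, and positions are those of mm10 with GENCODE M21.

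Short structural RNAs dominated the TPM scale. Rn7s1 and Rn7s2, identical copies of the RNA of the signal recognition particle, together took 38.0 ± 2.93% of all TPM but only 6.92 ± 0.794% of counts, because TPM divides by transcript length. Nuclear protein-coding genes took 37.4 ± 1.12% of TPM and 72.8 ± 0.176% of counts. Mitochondrial ribosomal RNAs held 7.23 ± 1.18% of counts and mitochondrial mRNAs 2.65 ± 0.231%. The 5 most abundant noncoding genes were Rn7s1 and Rn7s2 at 189771 ± 14644 TPM each, Rn7sk, a regulator of transcription elongation, at 27631 ± 1692, Gm26917, annotated as a lincRNA, at 12652 ± 2316, and the nuclear RNA Malat1 at 11932 ± 869. The fixed list of structural noncoding RNAs, in which Rmrp has 2 overlapping entries, had 11 entries detected and Rny3 listed at 0, with a median of 2713 ± 68.5 TPM.

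Genes of steroid hormone synthesis were the 4 most abundant nuclear mRNAs by mean TPM. Star, which delivers cholesterol to the inner mitochondrial membrane, stood at 5876 ± 1385 TPM (ENSMUSG00000031574.8, chromosome 8, 25806555 to 25815982, plus strand). Hsd3b1, the 3-beta-hydroxysteroid dehydrogenase, reached 5232 ± 130 TPM (chromosome 3, 98852194 to 98859794, minus strand). Cyp11a1, the side-chain cleavage enzyme that makes pregnenolone, reached 3592 ± 566 TPM (chromosome 9, 58006411 to 58027023, plus strand), and Cyp21a1, the steroid 21-hydroxylase, 3019 ± 345 TPM (chromosome 17, 34801348 to 34804561, minus strand). All 20 steroidogenesis genes were detected, with a median of 388 ± 32.1 TPM and a summed share of 6.75 ± 1.46% of nuclear coding TPM.

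Other leading coding genes mixed cortical enzymes with genes used by most cells. Cyp11b1, the 11-beta-hydroxylase that makes corticosterone, stood at 1818 ± 150 TPM and the transporter gene Abcb1b at 1438 ± 27.6. The steroid 5-alpha-reductase Srd5a2 reached 1432 ± 102 TPM, the aldo-keto reductase Akr1b7 1422 ± 1189, and Scarb1, the receptor that takes up cholesterol from high-density lipoprotein, 1031 ± 596. The translation factor Eef1a1 (2265 ± 19.7), Actb (1416 ± 172), the ferritin subunit Fth1 (1229 ± 85.4), the secretory granule protein Chga (1105 ± 142), Tpt1 (935 ± 3.10) and Gapdh (898 ± 126) filled the other places among the 15 most abundant coding genes. The 12 housekeeping genes were all detected, at a median of 256 ± 6.91 TPM, with Rpl13a at 589 ± 13.4.

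Genes of both main zones of the cortex were detected. The zona fasciculata list had the higher levels, but 7 of its 8 members are also in the steroidogenesis list, against 2 of 11 for zona glomerulosa. The medians therefore do not compare the zones themselves. All 8 zona fasciculata genes were detected at a median of 1353 ± 479 TPM, led by Star, Hsd3b1, Cyp11b1 and Abcb1b. All 11 zona glomerulosa genes were detected at a median of 78.4 ± 7.29 TPM. Among these the potassium channel Kcnk3 stood at 518 ± 5.09, the aldosterone synthase Cyp11b2 at 233 ± 41.9, Dab2 at 155 ± 8.90 and the angiotensin receptor Agtr1a at 152 ± 40.7. Cyp11b1 exceeded Cyp11b2 by 8.00 ± 2.09 times (chromosome 15, 74834125 to 74841643 and 74851010 to 74856318), but by 4.45 ± 0.577 times by kallisto, and the cause of this gap was not tested. X-zone markers, of the innermost cortex that regresses in male mice, were sparse. Akr1c18 stood at 0.110 ± 0.0566 TPM and Pik3c2g at 0.110 ± 0.156, while Thrb, also expressed elsewhere, reached 13.0 ± 0.679.

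Chromaffin cell genes formed the second clear signature. All 22 were detected at a median of 33.5 ± 4.02 TPM and made up 1.10 ± 0.270% of nuclear coding TPM. The granule proteins Chga (chromosome 12, 102554969 to 102565028), Chgb (chromosome 2, 132781278 to 132795079) and Scg2 (chromosome 1, 79434669 to 79440120) stood at 1105 ± 142, 723 ± 73.7 and 647 ± 100 TPM. Th, the first enzyme of catecholamine synthesis, stood at 385 ± 183 (chromosome 7, 142892752 to 142931128). The steroidogenesis median exceeded the chromaffin median by 11.6 ± 0.435 times within each gland. An exact paired permutation test over 2 animals cannot go below a p-value of 0.5, so none was run, and that ratio depended on the summary used (5.93 for geometric means). The ratio of Pnmt, which converts noradrenaline to adrenaline, to Th was 0.706 in replicate 1 and 0.305 in replicate 2.

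**Figure D1:**
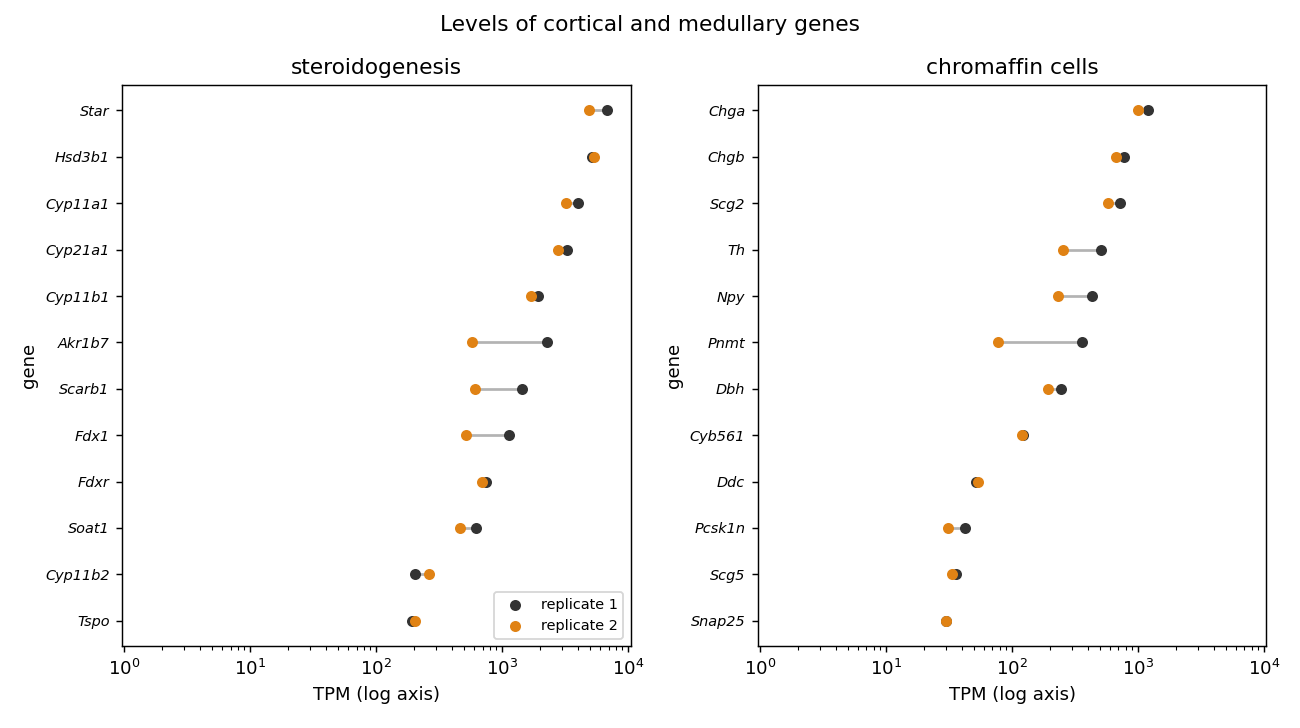
Levels of the 12 most abundant steroidogenesis genes (left) and the 12 most abundant chromaffin cell genes (right) in TPM on a log axis, with 1 point per replicate and a grey line joining the points of a gene. Star, Hsd3b1, Cyp11a1 and Cyp21a1 lie at 2775 TPM or more in both replicates.

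Genes of vessel, stromal and immune cells were also detected. Endothelial genes had a median of 39.4 ± 8.70 TPM (10 of 10 detected), with Plvap at 91.3 ± 2.19, Egfl7 at 80.5 ± 0.757, Emcn at 57.4 ± 0.148 and Kdr at 44.5 ± 2.11. Capsule and fibroblast genes had a median of 15.8 ± 5.83 TPM (10 of 10), led by Dcn at 98.6 ± 35.8, Nr2f2 at 47.0 ± 2.81, Col1a2 at 28.0 ± 9.30 and Col3a1 at 24.6 ± 16.4. Smooth muscle and pericyte genes had a median of 8.83 ± 1.72 TPM (7 of 8), with Tagln at 49.1 ± 22.2, Acta2 at 27.7 ± 19.4, Rgs5 at 13.3 ± 4.89 and Pdgfrb at 11.7 ± 3.59. Macrophage genes stood at a median of 11.8 ± 5.96 TPM (12 of 12), with the lysozyme gene Lyz2 at 136 ± 54.4 and the complement genes C1qb, C1qa and C1qc at 34.7 ± 4.21, 31.7 ± 6.01 and 25.2 ± 4.65. Class II genes had a median of 53.6 ± 0.870 TPM (7 of 7), led by Cd74 at 194 ± 10.5, H2-Eb1 at 73.2 ± 3.20, H2-Aa at 65.0 ± 3.25 and H2-Ab1 at 53.6 ± 0.870.

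Lymphocyte genes were near the detection limit, at a median of 0.315 ± 0.191 TPM (3 of 13 detected), with Ighm at 39.0 ± 26.9, Igkc at 22.9 ± 2.79, Jchain at 1.86 ± 0.446 and Cd3e at 0.810 ± 0.255. Schwann and sustentacular cell genes had a median of 1.48 ± 0.219 TPM (5 of 8), with Mbp at 7.42 ± 1.48, S100b at 7.31 ± 8.33 and Erbb3 at 1.74 ± 0.339. Globin genes, expressed by red blood cells, were abundant, with Hba-a1 at 686 ± 237, Hbb-bs at 625 ± 228, Hba-a2 at 471 ± 139 and Hbb-bt at 49.6 ± 22.4 TPM, and 5 of the 6 erythroid genes were detected at a median of 260 ± 80.6. By kallisto Hba-a2 stood at 207 and 322 TPM in replicates 1 and 2.

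Markers of neighbouring organs were low, whereas fat cell markers differed between the animals. None of the 10 kidney genes reached 1 TPM in both animals (0 of 10), and the highest, Aqp2, Miox, Kap and Slc12a3, stood at 0.645 ± 0.375, 0.315 ± 0.290, 0.180 ± 0.255 and 0.0300 ± 0.0424 TPM. Of the 8 pancreatic genes only Cela1 (40.0 ± 2.22) and Cpb1 (3.76 ± 0.0283) were detected, and Ins2 and Ctrb1 were listed at 0. Of the 7 skeletal muscle genes only Mylpf was detected, at 2.17 ± 0.184 TPM, beside Acta1 at 1.11 ± 0.757, Tnnt3 at 0.205 ± 0.290 and Atp2a1 at 0.0450 ± 0.0212. Liver genes had a median of 1.83 ± 0.0354 TPM (5 of 8), with Cyp2e1, which fat also expresses, at 32.4 ± 37.8, Alb at 7.89 ± 0.721, Mup3 at 2.42 ± 0.842 and Apoa2 at 2.08 ± 0.297. All 11 adipocyte genes were detected at a median of 82.6 ± 96.0 TPM (14.7 in replicate 1 and 150.4 in replicate 2), with Car3 at 358 ± 441, Fabp4 at 317 ± 361, Plin1 at 136 ± 104 and Lpl at 131 ± 145, and 2 of the 7 brown adipocyte genes were detected in both animals at a median of 24.5 ± 34.2. That median was 0.320 TPM in replicate 1 (liver markers 1.80 there) and 48.6 in replicate 2. In this group the SD exceeded the mean for Cox8b (59.0 ± 60.5), Ucp1 (40.4 ± 56.9) and Cidea (25 ± 34.8), but not for Cox7a1 (29.4 ± 27.3).

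Lists on cell state and sex gave the following levels. The 22 cholesterol synthesis genes were all detected at a median of 28.9 ± 16.4 TPM, led by Dhcr7 (348 ± 185), Msmo1 (115 ± 61.8), Fdps (98.1 ± 59.0) and Hmgcs1 (72.4 ± 21.3). The 10 heat shock genes had a median of 118 ± 51.1 TPM, led by Hspa8 (840 ± 367), Hspd1 (259 ± 79.0), Hsp90aa1 (208 ± 117) and Hspe1 (153 ± 34.8). Immediate early genes had a median of 9.36 ± 3.35 TPM (16 of 18), with Jun at 146 ± 16.6, Nr4a1 at 48.2 ± 42.8, Btg2 at 21.7 ± 0.926 and Dusp1 at 20.6 ± 6.22. Glucocorticoid target genes had a median of 30.1 ± 5.07 TPM (10 of 10), with the metallothioneins Mt2 and Mt1 at 92.4 ± 4.23 and 88.3 ± 1.45, Sgk1 at 73.1 ± 27.6 and Fkbp5 at 40.5 ± 0.551.

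Clock genes of the E-box phase had a median of 19.9 ± 0.594 TPM (10 of 10), led by Dbp (135 ± 24.4), Nr1d1 (97.0 ± 13.0), Tef (59.6 ± 10.5) and Nr1d2 (43.6 ± 6.35). Clock genes in antiphase to them stood at a median of 4.87 ± 1.73 TPM (5 of 6), with Clock at 17.4 ± 0.75, Arntl at 6.27 ± 2.45 and Cry1 at 3.46 ± 1.00. Interferon-stimulated genes had a median of 3.12 ± 0.718 TPM (11 of 12), with Rsad2 at 8.54 ± 1.92, Oasl2 at 5.75 ± 0.714 and Ifit3 at 4.20 ± 2.13. Proliferation genes were mostly under 1 TPM, with a median of 0.655 ± 0.198, only Top2a detected (1.59 ± 0.481), and Mki67 at 0.920 ± 0.240, Cdk1 at 0.890 ± 0.0990 and Plk1 at 0.695 ± 0.191.

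Imprinted genes, expressed from one parental allele, were prominent, with 17 of 18 detected at a median of 33.9 ± 0.926 TPM. Meg3 stood at 893 ± 22.3, Dlk1 at 453 ± 74.2, Rian at 435 ± 80.8 and Peg10 at 102 ± 24.3. Replication-dependent histone genes, whose mRNAs lack a poly(A) tail, had a median of 7.30 ± 1.36 TPM (11 of 14), with Hist1h4h at 158 ± 0.615, Hist1h1c at 75.2 ± 27.3, Hist1h4d at 43.8 ± 1.09 and Hist1h2bc at 40.4 ± 1.74. The 4 Y-linked genes were all detected at a median of 23.9 ± 0.820 TPM, with Eif2s3y at 34.2 ± 3.10, Ddx3y at 32.2 ± 2.38, Uty at 15.6 ± 0.735 and Kdm5d at 8.16 ± 0.658. Xist, the RNA of the inactive X chromosome, stood at 0.0250 ± 0.00707 TPM, in libraries labelled male.

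The replicates were similar across genes but differed in defined groups. Over 18196 genes with a mean of at least 10 counts, log2(CPM + 1) correlated with r = 0.982 and rho = 0.979 across genes, which are not independent replicates. Of 12853 nuclear genes with at least 100 counts, 307 were at least 2-fold higher in replicate 2 (284 coding) and 148 at least 2-fold lower (90 coding). At 4-fold, 114 genes were higher and 22 lower. Among the genes that differed, 13.8% had an uncertain estimated count, against 3.28% of all genes compared. Each side is 1 animal, so these differences have no replicate check.

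Of the 12 highest ratios, 4 belonged to members of the fixed fat lists (Ucp1, Cidea, Cfd and Car3). Ucp1, the uncoupling protein of brown fat (chromosome 8, 83290352 to 83298452), had 6 counts in replicate 1 and 3727 in replicate 2, a 530-fold difference (243 to 1444). Cidea, a lipid droplet protein of brown fat, was 118-fold higher (65.5 to 236), the proton channel gene Otop1 33.0-fold (20.1 to 58.1), Pck1 20.8-fold (18.8 to 23.1), Thrsp 18.6-fold (16.2 to 21.5) and Cpt1b 18.0-fold (13.8 to 24.0, an uncertain count). Cfd (adipsin) was 14.3-fold higher (11.9 to 17.2), the carboxylesterase Ces1d 14.0-fold (12.2 to 16.1) and the carbonic anhydrase Car3 13.3-fold (12.7 to 13.9). The other 3 of the 12 highest, Fam177a and the identical entries Gm10240 and Gm13370, had uncertain counts. Fam177a was 102-fold higher by RSEM (43.3 to 314) but had a log2 ratio of 0.16 by kallisto. With their count of 0 set to 3, Gm10240 and Gm13370 were each 122-fold higher (lower end of the interval 99.2). Their log2 ratio by kallisto was 3.22.

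The lowest ratios mixed genes on which the quantifiers were close with genes on which they were far apart. Erfe, which encodes erythroferrone, was 6.83-fold lower in replicate 2 (5.79 to 8.09), Pnmt 5.08-fold (4.87 to 5.31) and the immediate early gene Nr4a1 5.0-fold (4.68 to 5.35), with log2 ratios of -2.54, -2.33 and -2.28 by RSEM and -2.49, -2.26 and -2.24 by kallisto. The other 9 had uncertain counts. With counts that rounded to 0 set to 3, Gm12070 was 809-fold lower (lower end of the interval 658) and Rpl7a-ps11 80.6-fold lower (lower end 64.9). The gene 1700047I17Rik2 was 22.5-fold lower (15 to 35.5) and Gm20388 10.2-fold lower (8.46 to 12.4). The small nucleolar RNA copies Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4 were each 7.01-fold lower (6.01 to 8.21) and Gm10222, a nuclear copy of mitochondrial sequence, 5.97-fold (5.12 to 6.98). By kallisto the log2 ratios of Gm12070, Gm20388 and Rpl7a-ps11 were -0.78, -0.66 and -0.40. Those of the other 6 were 0 only because kallisto listed these genes at 0 TPM in both replicates, so it gave no comparison for them.

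**Figure D2:**
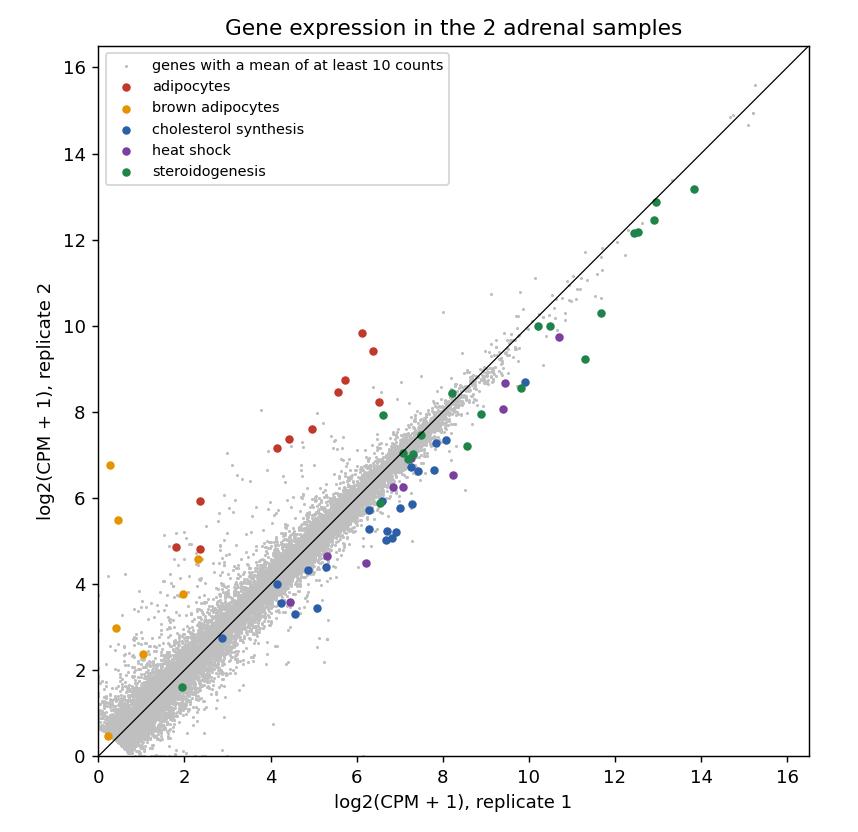
Log2(CPM + 1) of each gene in replicate 2 against replicate 1, with members of 5 gene lists in colour and a line of equal levels. The 11 adipocyte genes lie above that line, and the 22 cholesterol synthesis genes below it.

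Fat cell genes stood apart as a group. All 11 adipocyte genes were at least 2-fold higher in replicate 2, with a median log2 ratio of 3.0, above all 10000 matched random lists. Retn (resistin) was 11.4-fold higher (8.98 to 14.7) and Lpl, the lipoprotein lipase, 8.26-fold (7.92 to 8.62), beside Car3 and Cfd. All 6 measured brown adipocyte genes were at least 2-fold higher, with a median of 2.42, also above all random lists, and included the deiodinase Dio2 (20.5-fold, 10.9 to 43.2) and Cox8b (5.75-fold, 4.73 to 7.04). Of the 29 lists placed among random lists, 7 lay above and 8 below their range. For lists of unrelated genes, chance would put 1.45 outside. Random lists hold genes drawn singly, so that number does not apply to lists whose members vary together. The 15 lists outside are not separate results either, since zona fasciculata shares 7 of its 8 members with steroidogenesis. Counts of members higher or lower here and below go by their log2 ratios, whether or not the counting interval includes equality.

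Erythroid, macrophage and stromal genes were also higher in replicate 2, by less. The erythroid median was 0.61 (6 of 6 higher, 5 with an interval above equality, percentile 99.98), with Hbb-bt 1.78-fold higher (1.61 to 1.97), Alas2 1.74-fold (1.5 to 2.03), Hbb-bs 1.54-fold (1.5 to 1.59) and Hba-a1 1.52-fold (1.48 to 1.56). The macrophage median was 0.51 (11 of 12 higher, and Cd14 too when scaled to spike-ins or totals, above all random lists), with Gpnmb 2.05-fold higher (1.86 to 2.27), Cd68 1.77-fold (1.52 to 2.07), Trem2 1.74-fold (1.43 to 2.12) and Lyz2 1.63-fold (1.57 to 1.70). Capsule and fibroblast genes had a median of 0.32 (9 of 10 higher, percentile 99.93), with Col3a1 3.04-fold higher (2.86 to 3.23), Col1a1 2.01-fold (1.89 to 2.13), Col1a2 1.56-fold (1.49 to 1.63) and Dcn 1.54-fold (1.48 to 1.61). Fat cell genes were higher in the same replicate, but 2 libraries cannot show whether these groups vary with them.

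Cholesterol synthesis genes were lower in replicate 2. All 22 had lower values, 20 with an interval below equality (not Ebp and Pmvk) and 11 at least 2-fold, with a median log2 ratio of -0.94, below all random lists. Cyp51, the lanosterol demethylase (chromosome 5, 4081145 to 4104746), was 3.43-fold lower (3.20 to 3.67), Idi1 3.36-fold (3.15 to 3.59), Hsd17b7 3.28-fold (2.90 to 3.72) and Sqle, the squalene epoxidase, 3.22-fold (3.01 to 3.45). Steroidogenesis genes had a median of -0.35 (18 of 20 lower, 4 at least 2-fold), below all random lists; scaled to spike-ins, 15 were lower and Hsd3b1, Por and Tspo turned slightly higher. Akr1b7 was 4.25-fold lower (4.18 to 4.31) and Scarb1 2.62-fold (2.60 to 2.65), whereas the hormone-sensitive lipase Lipe, also expressed in fat, was 2.51-fold higher (2.41 to 2.62). All 8 zona fasciculata genes, of which only Abcb1b is not in the steroidogenesis list, were lower (7 when scaled to spike-ins, without Hsd3b1), with a median of -0.48 (percentile 0.01), among them the corticotropin receptor accessory protein Mrap (1.59-fold, 1.5 to 1.68) and Star (1.58-fold, 1.57 to 1.58). The replicate with the lower values also held the higher fat cell signal.

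Stress-induced genes were lower in that same replicate, beside its higher fat cell signal. All 10 heat shock genes were lower, with a median log2 ratio of -0.85, below all random lists. Hspa1b was 3.41-fold lower (3.14 to 3.72), Hsph1 3.29-fold (3.15 to 3.42), Hsp90aa1 2.49-fold (2.43 to 2.55) and Hspa8 1.95-fold (1.93 to 1.98). Immediate early genes had a median of -0.52 (13 of 18 lower, below all random lists), with Fos 3.42-fold lower (2.86 to 4.09), Fosb 2.42-fold (1.89 to 3.12) and Klf4 2.13-fold (1.90 to 2.40) beside Nr4a1.

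Most medullary genes were lower in replicate 2, the library with the higher fat cell signal. Chromaffin genes had a median of -0.24 (17 of 22 lower, below all random lists). The counting interval lay below equality for 16 of them and above it for 4. The members furthest from equality were Pnmt, 5.08-fold lower, Th 2.20-fold (2.15 to 2.24) and Gch1, which makes a cofactor of Th, 1.93-fold (1.82 to 2.05), and the neuropeptide gene Npy, 2.00-fold lower (1.92 to 2.09). Other enzymes of catecholamine synthesis, named outside the rule, were nearer to equality, with log2 ratios of -0.45 for Dbh and 0.06 for Ddc.

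Clock genes of opposite phase differed in opposite directions, between libraries that also differed in fat cell genes (adipocyte median 3.0). Those in antiphase to the E-box phase were lower in replicate 2 (6 of 6, or 5 when scaled to spike-ins or totals; 4 with an interval below equality; median -0.43, percentile 0.160), with Arntl 2.05-fold (1.80 to 2.34), Cry1 1.64-fold (1.38 to 1.96) and Nfil3 1.59-fold lower (1.29 to 1.96), and Npas2 1.36-fold lower with an interval that includes equality (0.939 to 1.97). Those of the E-box phase were higher (8 of 10, median 0.21, percentile 99.52), with Ciart 2.05-fold (1.43 to 2.97), Per3 1.30-fold (1.21 to 1.39) and Hlf 1.26-fold higher (1.14 to 1.39). Per2 went the other way, 1.65-fold lower (1.58 to 1.74).

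Proliferation and imprinted genes also lay outside the random range, again beside that fat cell signal. All 12 proliferation genes had higher values in replicate 2, but only 4 with an interval above equality (median 0.29, percentile 99.21), at low counts, with Aurkb 2.13-fold (1.17 to 4.08), Top2a 1.47-fold (1.13 to 1.90), Cenpf 1.44-fold (1.04 to 2.01) and Mki67 1.33-fold higher (1.11 to 1.59). The TPM of Cenpf went the other way, 0.83 in replicate 1 and 0.42 in replicate 2. With coding genes alone as background the proliferation median lay inside the random range. Imprinted genes had a median of -0.17 (12 of 18 lower, percentile 1.25), with Peg10 1.53-fold (1.5 to 1.56), Rian 1.43-fold (1.4 to 1.46) and Dlk1 1.37-fold lower (1.34 to 1.4), and Nnat 2.02-fold higher (1.87 to 2.18).

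**Figure D3:**
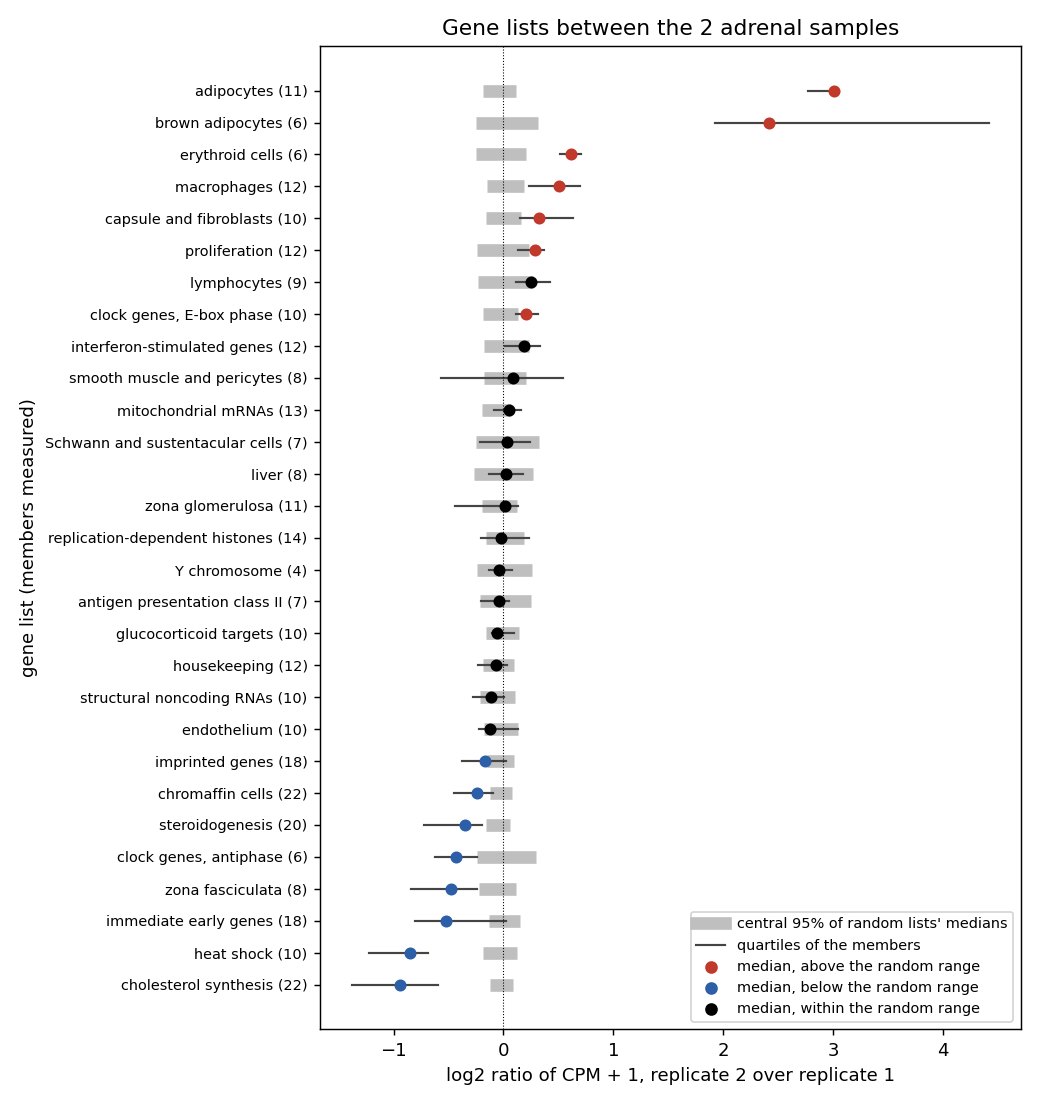
Median log2 ratio of replicate 2 over replicate 1 for each gene list (points, with thin lines for the quartiles of its members) and the central 95% of the medians of 10000 matched random lists (grey bars); brackets give the members measured. Adipocyte genes lie at 3.0 and cholesterol synthesis genes at -0.94, outside the random range on either side.

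The other 14 lists lay within the random range. Their median log2 ratios were 0.01 for zona glomerulosa, 0.03 for Schwann and sustentacular cells, -0.12 for endothelium, 0.08 for smooth muscle and pericytes and 0.25 for lymphocytes. Class II antigen presentation stood at -0.04, liver at 0.02, glucocorticoid targets at -0.06, interferon-stimulated genes at 0.19 and mitochondrial mRNAs at 0.05. Y-linked genes stood at -0.04, housekeeping genes at -0.07, structural noncoding RNAs at -0.12 and histones at -0.02. Nuclear members of these lists that were at least 2-fold apart with a mean of at least 100 counts are named here after their values were seen. Acta2 was 3.18-fold and Tagln 2.45-fold lower in replicate 2, while Cyp2e1 was 9.39-fold, S100b 8.52-fold, Ighm 2.65-fold and Cldn5 2.02-fold higher. X-zone, kidney, pancreas, skeletal muscle and X inactivation had fewer than 3 measured members and were not placed.

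The quantifiers gave close values for most coding genes and different values for short and repeated RNAs. Across genes, log2 TPM by RSEM and kallisto correlated with r = 0.960 in replicate 1 and 0.963 in replicate 2. Of 14642 genes compared, 472 were at least 2-fold higher by RSEM and 561 by kallisto, 7.06% in all. Among 12575 coding genes these numbers were 57 and 120, or 1.41%. Small RNAs were higher by RSEM, with 78 of 80 snoRNAs, 30 of 30 snRNAs and 25 of 25 miRNAs on that side. The genes furthest to that side were the ribozyme entry of Rmrp, the RNA of RNase MRP, at 2643 ± 141 TPM by RSEM, and the snRNA entries Gm24265 (1312 ± 473), Gm24407 (1307 ± 690), Gm26444 and Gm23804 (both 846 ± 133), all listed at 0 by kallisto. In the other direction, Gm19220, Rpl36a-ps3, Gm47283 and Gm49274 were listed at 0 by RSEM and at 440, 99.4, 67.9 and 51.9 TPM by kallisto in replicate 1, and Gm28439 at 0 and 117 TPM.

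All 13 mitochondrial mRNAs were detected, at a median of 1741 ± 176 TPM, but several depended on how reads were divided with nuclear copies of mitochondrial sequence. The cytochrome oxidase subunit mt-Co1 led at 7995 ± 700 TPM, followed by mt-Cytb at 3661 ± 412, mt-Nd1 at 2947 ± 51.8 and mt-Co3 at 2722 ± 1382. Outside the rule for named genes, mt-Co2 was listed at 2888 and 1865 TPM by RSEM and at 330 and 700.4 TPM by kallisto in replicates 1 and 2. The short overlapping gene mt-Atp8 stood at 1010 ± 47.0 TPM by RSEM and at 1.76 and 1.67 TPM by kallisto.

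ERCC spike-ins took nearly the same share of both libraries. They held 72970 counts in replicate 1, 0.243% of all counts (0.241 to 0.244), and 80865 in replicate 2, 0.237% (0.236 to 0.239). There were 411 gene counts per spike-in count in replicate 1 and 420.3 in replicate 2, and 61 and 60 of the 96 spike-ins had a count above 0.

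Most leading adrenal genes were expressed as 1 main transcript. Cyp11a1-201 took 98.3 ± 0.184% of its gene's TPM, Cyp21a1-201 96.7 ± 0.758% and Chga-201 97.1 ± 0.370%, while Chgb-201 is the gene's only annotated transcript. Star was divided, with Star-202 at 51.2 ± 1.37%, as was Scg2, with Scg2-202 at 61.4 ± 5.28%, and Hsd3b1-201 took 71.6 ± 1.35%. Th-201 took 100% by RSEM but 88.6% and 82.5% by kallisto, and Cyp11a1-201 82.3% and 83.3%.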

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

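Signal outside the main measurement was found in both libraries, and no further tests were run on it. The entry of phiX174, a bacteriophage genome added to sequencing runs as a control, held 87 counts in replicate 1 and 110 in replicate 2, or 2.89 and 3.23 CPM. The 26248 entries named by a bare number held 4.56 counts in replicate 1 and 6.27 in replicate 2, spread over 3 and 2 entries, of which the highest held 2.56 and 3.27 counts. In replicate 1 no single numbered entry exceeded the 3 counts that a count of 0 allows, and in replicate 2 only 1 did. With 2 animals, no rule on single deviating samples applied.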

How the results depend on the processing

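No list outside the random range changed direction in the alternatives run. Alternatives restricted to well-determined counts, without fat-expressed members, with the GC content and length trend removed, and with coding genes as background were chosen after seeing the data. Rescaling shifts a list and its matched random lists nearly alike, so it can hardly move a list across the random range. Leaving out near-identical copies or fat-expressed members changes nothing for lists that have none. With such cases counted in, 280 of 285 alternatives for the list medians kept their side of the random range. The median changed sign in 13, all in lists within that range under both settings (Schwann and sustentacular cells, class II antigen presentation, liver, glucocorticoid targets, Y-linked genes, housekeeping genes and histones). Lymphocytes moved above it without a count filter (0.25) and with the GC and length trend removed (0.34), interferon-stimulated genes by kallisto (0.22), and mitochondrial mRNAs with that trend removed (0.12). Proliferation (0.29) moved inside it with coding genes as background. The cause was not tested. The numbers of genes 2-fold higher and lower in replicate 2 were 865 and 712 at a minimum of 10 counts, 1086 and 971 with no minimum, 795 and 502 at 1.5-fold and 114 and 22 at 4-fold; low counts and thresholds set these numbers by construction. Under 4 scalings they ranged from 307 to 349 and from 119 to 150, and the median of all genes shifted by at most 0.07. By kallisto, 272 of the 307 higher and 107 of the 148 lower genes were the same. On nuclear coding genes alone, steroidogenesis took 6.75% and chromaffin genes 1.10% of TPM, with medians of 1039 and 89.8 TPM, by construction. The chromaffin median was 28.8 TPM by kallisto. The ratio of steroidogenesis to chromaffin levels was 6.18 from sums, 5.93 from geometric means and 13.2 by kallisto. The correlation of the replicates was 0.972 with pseudocount 0.1, 0.993 without filter, 0.978 on TPM and 0.984 by kallisto. Genes apart between the quantifiers numbered 427 at 5 TPM and 3351 at 0.1 TPM. Spike-ins took 0.208% and 0.205% by kallisto. Of the alternatives for single named genes, 249 stayed within the counting interval and 55 moved, none with a change of sign. The ratios of 6 genes with uncertain counts went to 0 by kallisto, which listed them at 0 TPM in both replicates. Among mitochondrial mRNAs, mt-Co2 changed sign, from -0.76 by RSEM to 0.97 by kallisto. Leaving out either replicate keeps a mean of 2 within 1 SD by construction, so it shows nothing about stability. No value could be had for erythroid genes and histones without near-identical copies, fat lists without fat-expressed members, or structural RNAs against coding genes. No paired analysis was possible between groups of samples because there is 1 group. Depth limits genes below about 10 counts, such as those of kidney and X-zone.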

Other observations

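The 6 further lists, the choice of the 4 independent lists and the tests on scaling, dilution, mt-Atp6 with mt-Co2 and mt-Co3, and mt-Nd3 were chosen only after the main results were seen; Srd5a2 had been seen among the most abundant genes. Receptors for hormones and transmitters were led by Insr (58.5 ± 9.12 TPM), Igf1r (32.2 ± 2.77), Prlr (28.1 ± 1.81) and Adcyap1r1 (26.1 ± 3.92), with 8 of 14 detected and a median log2 ratio of replicate 2 over replicate 1 of -0.00, within the random range. Nicotinic receptor subunits, through which nerves stimulate the medulla, were detected for Chrna3 (15.8 ± 1.97), Chrna7 (12 ± 1.2), Chrnb4 (8.05 ± 0.240) and Chrnb2 (2.81 ± 0.00707), but not for Chrna5 (0.525 ± 0.0636). Their median log2 ratio of -0.16 lay within the random range. Chrna3 and Chrna7 were 1.28-fold lower in replicate 2, while the intervals of Chrnb4, Chrnb2 and Chrna5 included equality. Among steroid-converting enzymes, Srd5a2 stood at 1432 ± 102 TPM, Hsd11b1 at 26.6 ± 4.91, Srd5a1 at 3.24 ± 0.247 and Cyp17a1, the 17-alpha-hydroxylase, at 5.70 TPM in replicate 1 and 1.43 in replicate 2, 4.36-fold lower in the latter. The list median was -0.03, within the random range.

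Genes of WNT signalling and cortical progenitors were the only further list outside the random range, at a median of -0.20 (percentile 1.07, 9 of 12 lower in replicate 2, or 7 of 12 when scaled to spike-ins). Replicate 2 also held the higher fat cell signal, and the 4 cortical enzymes Cyp11a1, Hsd3b1, Cyp21a1 and Cyp11b1 had a lower median still, -0.33. Zona glomerulosa genes had a median of 0.01. Ctnnb1 stood at 337 ± 16.0 TPM, Gata6 at 33.5 ± 0.976, Axin2 at 32.2 ± 0.127 and Lgr5 at 22.7 ± 0.792, while Gata4 was 4.47-fold lower in replicate 2 from 61 and 16 counts and Lef1 1.44-fold lower. Lipid droplet and sterol transport genes had a median of 0.06 within the random range, but members went apart. The cholesterol exporter Abca1 was 1.89-fold higher in replicate 2 (1.84 to 1.93) and Abcg1 1.48-fold (1.35 to 1.64), while Npc1 was 1.42-fold lower; Apoe stood at 357 ± 81.0 TPM and Plin2 at 123 ± 11.7. Antioxidant enzymes had a median of 0.07 within the random range, with Sod1 at 399 ± 29.6, Prdx3 at 271 ± 20.7, Prdx1 at 263 ± 9.74 and Gpx4 at 261 ± 38.1 TPM, and Gpx3 was 1.73-fold higher in replicate 2. The annotation holds 2 entries named Nnt, both counted, with log2 ratios of -1.24 (2.45-fold lower) and 0.12 by RSEM but 0.09 and -0.48 by kallisto.

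Higher fat cell genes in replicate 2 were weighed against scaling and against fat in the dissected sample. The adipocyte median was at least 3.0 under each of 4 scalings, so the choice among these is not the cause. They lie close together, with a median log2 ratio of all genes of 0.07 or less under each. The test could therefore hardly have come out otherwise. Independent fat genes, none in the fixed lists, had a median log2 ratio of 1.73 with 16 of 20 at least 2-fold higher, among them Dgat2 (7.66-fold), Aoc3 (6.97-fold), Cd36 (4.61-fold) and Fasn (3.08-fold), above all random lists, although the gland itself expresses some of them (Fasn at 86.4 TPM in replicate 1). The most abundant markers stood at 358 ± 441 (Car3) and 317 ± 361 TPM (Fabp4), so a candidate source is fat around the gland, including brown fat, taken with the gland of replicate 2. The design names no biological difference between the animals, so none was tested.

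Lower cholesterol synthesis genes in replicate 2 could reflect dilution by fat RNA, but the list median minus that of the 4 cortical enzymes Cyp11a1, Hsd3b1, Cyp21a1 and Cyp11b1 (-0.33) was -0.61, which argues against dilution as the whole cause. A bias of GC content or transcript length is likewise argued against, since the median was -0.94 with that trend removed. Independent sterol targets (median -0.22, 7 of 8 lower or 6 when scaled to spike-ins or totals, percentile 0.850, with Stard4 1.78-fold lower) and independent cAMP targets (median -0.24, 6 of 9 lower, percentile 0.690, with Sik1 1.62-fold lower and Sik2 1.92-fold higher) lay below the random range but short of the bound of -0.3 set in advance. Both medians were thus lower than those of random lists, but by less than the bound. Weaker sterol-regulated transcription and a weaker cAMP-type stimulus were therefore left undecided. The hour and manner of tissue collection are not stated in the labels and were not tested.

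For mitochondrial mRNAs with a near-identical nuclear copy, division of reads with the copy was weighed. Summed with the genes that share at least 50% of their sequence words of 31 bases, 5 of 7 had log2 ratios within the range of the mRNAs without a copy (-0.16 to 0.16), which left the question open for the group. Of the 5, mt-Co1 and mt-Nd4 had been inside the range before summing and do not test it. Outside it lay mt-Nd3 and mt-Nd4l, and summing mt-Nd4l with Gm10222 took it from -0.08, inside the range, to -0.24, against this cause. For mt-Atp6, mt-Co2 and mt-Co3, whose own log2 ratios were 0.98, -0.76 and 0.96, the sums with Gm10925, Gm28661 and Gm28437 reached at most 0.0778, so division of reads may account for their differences. For mt-Nd3 the copy Gm28438 held 0 counts in both libraries by RSEM, so the sum is its own log2 ratio of 1.00 (1.16 by kallisto). A count of 0 is how RSEM assigned reads and does not show that none were shared. The sum does not depend on how reads are divided between mt-Nd3 and Gm28438. Its value therefore argues against division with that copy as the cause for mt-Nd3. No biological explanation was tested.

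A hypothesis that lower heat shock genes in replicate 2 are part of a wider chaperone response was tested on 12 independent chaperones. Their median log2 ratio was -0.63 with 11 of 12 lower, below all random lists, including Stip1 (2.09-fold lower), Chordc1 (1.68-fold) and Fkbp4 (1.62-fold), while Cryab was 1.5-fold higher. The values are consistent with a shared response in these 2 libraries. The same library held the higher fat cell signal (adipocyte median 3.0), and dilution by fat RNA may account for part of the value. How much is not known, since gland genes did not fall alike. The 4 cortical enzymes had a median of -0.33 and the zona glomerulosa list one of 0.01. The cause was not tested.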
